A study of Mus musculus with 6 samples.

How the data were processed

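Total RNA from the livers of male C57BL/6J mice was measured on Agilent whole-genome mouse arrays with a single dye, Cy3. C57BL/6J is an inbred laboratory strain. Per the labels' protocols, the mice were 8 weeks old when they were allocated at random to a diet and were killed 12 weeks later. The CFD diet held no choline and no folic acid and 0.17% methionine. The control diet had the same base, with folic acid added at 2 mg/kg, choline bitartrate at 0.3% and methionine at 0.4%. There were 3 arrays of control livers and 3 of CFD diet livers, and groups were taken from the labels. The labels number the replicates of a group and do not state that each came from a separate mouse, so the p-values measure the spread between these samples, which may be partly technical.

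The deposited scanner files give an intensity for every spot, already background-subtracted by Agilent's Feature Extraction software (the processed signal), per the file headers. The headers name version 10.5.1.1 of that software, and the submitters' processing notes name version 10.7. The deposited value table of the series holds intensity values on a linear scale, whose 75th percentile on each array lay near 1000. Its column medians were 67.98, 61.49 and 67.63 for the columns named control 1 to 3 and 72.67, 73.88 and 80.59 for those named CFD diet 1 to 3. It was set against the scanner files by rank. Each of its columns had a rank correlation of 1 with another replicate of its own group. The column named control 1 held the values scanned as control 2, control 2 those of control 3, and control 3 those of control 1, and the CFD diet columns were shifted in the same way. The groups are the same in both sources. Replicates are numbered here by the scanner files, and the value table served only as an alternative. No centring of genes was seen in that table, and which of the replicate numberings is the intended one stays unknown. No column of per-sample values was left unmapped (0 columns).

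The array holds 41174 probes besides its control spots. The number of probes well above background, by the software's own flag, was 26270, 22840 and 21689 on control arrays 1 to 3 and 29044, 23585 and 25090 on CFD diet arrays 1 to 3. The 75th percentile of the processed signal was 438.8, 365 and 402.2 on the control arrays and 617.8, 404.1 and 670.2 on the CFD diet arrays. The replicated spots of an array had a median coefficient of variation between 3.98% and 4.85%. No spot was saturated. The number of arrays limits the precision of every value. Replicates with the same number shared a slide and a scan, so each of the 3 slides held 1 control and 1 CFD diet liver.

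Signals were put on the log2 scale and each array's 75th percentile over the spots that are not controls was subtracted. Control spots and outlier spots were left out, and spots of a probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 23482 probes. A gene was represented by its tested probe with the highest mean over all 6 arrays, which gave 15909 genes, 38 of them with a missing value on an array. Of 5499 genes with more than 1 tested probe, 2221 had at least 2 probes called, and 171 of these had probes called in both directions. Gene names were updated through a RefSeq table of the mouse assembly GRCm38.p6. By that table, 22951 probes were named through an accession, 6659 had a current symbol, 3109 had an older symbol and 8455 kept the name in the file. Of the tested genes, 13549 had a name in that table. Probe coordinates are those of the files, in build mm7 (NCBI35) per the file headers.

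The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by the method of Benjamini and Hochberg. A gene was called at an adjusted p below 0.05. Errors beside log2 fold changes are standard errors from limma, with 3 arrays in each group. Where a gene was not well above background on any array of a group, only a bound is given, as "at least N-fold". On the processed signal, it sets the brighter group's mean against the mean, in the dimmer group, of the higher of the array's lowest well-above-background signal and the probe's own value. The comparison of 33 gene lists, fixed before the data were examined, used limma's camera test, which sets the genes of a list against all other genes, with a preset correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation and limma's fry test were run beside it. Fry asks whether the genes of a list move, on balance, in a single direction, and does not set the list against other genes. Calls of members are given over all tested genes and adjusted over the list alone. The 33 lists share some genes, such as 10 genes on both the cytochrome P450 and the female-biased list and 5 on both the cholangiocyte and the fetal and tumour list.

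The genes named in the text were set by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes whose 3 CFD diet values all lie on one side of the 3 control values, passing over clone and predicted-gene names, and for each list the 4 tested members with the smallest p. Members named as exceptions to the direction of their list, and a few others marked in the text, were chosen after their values were seen. Some genes that the rule names are not reported.

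The alternatives chosen in advance were normexp background correction (offset 50) on the mean and local background signals, quantile normalization, scaling to the array median, no filter on dim probes, a filter on all 6 arrays, the value table, the replicate number (which is also the slide) as a block, the slide as a random block, the mean of a gene's probes, every probe counted, eBayes with trend and robust settings, array weights, and leaving out each array in turn. Centring on the median of the tested genes and gene families by symbol stem were added after seeing the data.

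The script was tested on simulated data drawn from the means and spreads of 15881 genes without missing values, with 200 genes changed. For the comparison of CFD diet with control, 3 of 67 genes changed 1.5-fold were recovered, 32 of 67 changed 2-fold and 53 of 66 changed 4-fold, and 3 of the 91 calls were false. The median estimated folds were 1.50, 2.01 and 4.02. In the same comparison on 15881 genes, camera called a simulated list of 30 genes raised 2-fold and 0 of the 20 lists left alone. The simulated genes were drawn independently of each other, so this does not test camera on lists of correlated genes. With 200 genes changed, the recovered shares need not hold where many more genes change. Plots were drawn with matplotlib 3.10.9.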

Results

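Gene expression was measured in the livers of male mice kept for 12 weeks on a control diet (3 arrays) or on the CFD diet (3 arrays), which lacks choline and folic acid and is low in methionine. The comparison asks which genes differ in liver expression after this diet. Between 21689 and 26270 of 41174 probes were well above background on the control arrays, and between 23585 and 29044 on the CFD diet arrays. Across genes, which are not independent replicates, arrays of the control group correlated at 0.990 to 0.993 and arrays of the CFD diet group at 0.982 to 0.990. Pairs of arrays from different groups correlated at 0.913 to 0.951.

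The expression of the liver changed widely on the CFD diet. Matrix metalloproteinases, keratin 20 and genes of activated macrophages were among the largest rises, and steroid-metabolizing enzymes and a hepatic uptake transporter were among the largest falls. By limma with adjusted p below 0.05, 8129 of 15909 tested genes (51.1%) changed, 3776 higher and 4353 lower in the CFD diet livers. Of these, 3910 changed at least 2-fold, 2355 upward and 1555 downward. With normexp background correction, whose offset draws dim values together, 2189 genes changed at least 2-fold. Genes lower in the CFD diet livers numbered 2459 without the filter on dim probes, 2746 without control replicate 3 and 2844 without CFD diet replicate 3. All 3 CFD diet values lay on one side of the 3 control values for 10023 tested genes (63%), where chance gives 10%, and 7319 genes were called with the slide as a block. The split into higher and lower calls moved with the scaling. It was 2934 higher and 5814 lower after scaling to the array median, which lowered the median log2 fold change of all tested genes from -0.11 to -0.31, so directions are relative to the scaling.

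Krt20, an intermediate filament keratin of intestinal and other epithelia, had the highest fitted rise on the processed signal, 8.85 ± 0.92 on the log2 scale (adjusted p = 0.000626), although controls 2 and 3 were not well above background. Gpnmb, a transmembrane glycoprotein of macrophages, rose by 8.50 ± 1.04, Sult1e1, the estrogen sulfotransferase, by 8.50 ± 0.86 and Tinag, a basement membrane antigen, by 8.01 ± 0.65. Mmp7 and Mmp12, which encode matrix metalloproteinases, rose by 7.81 ± 0.79 and 7.78 ± 0.55. Wfdc3 rose by 7.73 ± 0.75, the iron-siderophore binding protein Lcn2 by 7.06 ± 0.59 and Ly6d by 6.90 ± 0.48. Among these 9 genes, the largest adjusted p by limma was that of Gpnmb, at 0.00121. In the control group, Sult1e1 and Ly6d were well above background on 3 arrays, Gpnmb, Wfdc3 and Lcn2 on 2 arrays, and Krt20, Tinag, Mmp7 and Mmp12 on 1 array, control replicate 1, so the fitted sizes and ranks of these 4 rest on signals at background and on that array. Without that array, the rise of Sult1e1 was 9.56. With normexp the rise of Sult1e1 was the largest of the 9, at 7.59, while Krt20 rose by 5.55, Tinag by 4.49 and Mmp12 by 4.14. A second probe for Wfdc3 gave 0.44 ± 0.18 (adjusted p = 0.158) in a fit of all probes, so the rise of this gene depended on the probe. A second probe for Gpnmb, well above background on 3 CFD diet arrays and 0 control arrays, was at least 3.10-fold higher, with a smaller fitted rise than the first. In build mm7, the Krt20 probe lies on chromosome 11 from 99537501 to 99537560, and the Mmp7 and Mmp12 probes lie on chromosome 9 from 7695434 to 7695493 and from 7352125 to 7352640.

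The largest fall on the processed signal was that of Slco1a1, an organic anion uptake transporter of hepatocytes and a male-biased liver gene, by -7.13 ± 2.07 on the log2 scale (adjusted p = 0.0265). Hsd3b5, a male-biased hydroxysteroid dehydrogenase, changed by -6.21 ± 1.79 and Hsd3b4 by -5.18 ± 1.32. The non-coding Hnf4aos changed by -6.42 ± 1.89, Serpina4-ps1 by -5.71 ± 1.22, Dct by -5.64 ± 1.64 and Clec2h by -5.27 ± 1.30. Rd3, Lrit2 and Sntg2 changed by -5.15 ± 1.33, -5.14 ± 1.30 and -4.83 ± 1.15. The adjusted p of these 10 genes lay between 0.00869 for Serpina4-ps1 and 0.0276 for Hnf4aos. The large errors came from the CFD diet livers, whose standard deviation was 4.64 for Slco1a1 and 4.01 for Hsd3b5 against 0.15 and 0.21 in the controls. Within slides 1, 2 and 3, Slco1a1 differed by -9.97, -1.62 and -9.80 and Hsd3b5 by -8.94, -1.86 and -7.83. Without CFD diet replicate 2, Slco1a1 changed by -9.81 and Hsd3b5 by -8.50. Leaving out any other array ended the call of Slco1a1, Hnf4aos, Hsd3b5 and Dct, with adjusted p by limma of 0.0636 to 0.0877 for Slco1a1 and 0.0634 to 0.0934 for Hnf4aos. Without CFD diet replicate 3 the calls of Clec2h, Hsd3b4, Rd3 and Lrit2 ended too, at adjusted p by limma of 0.0555, 0.0604, 0.0625 and 0.0603. The call of Rd3 also ended without control replicate 3, at an adjusted p of 0.0523, and without CFD diet replicate 1, at 0.0510. The calls of Slco1a1, Hnf4aos, Hsd3b5 and Dct also ended with trend and robust settings, and without the filter on dim probes all but those of Serpina4-ps1 and Sntg2 ended. With normexp, Hsd3b5 (-5.66) and Hsd3b4 (-4.97) fell further than Slco1a1 (-4.46), and Hnf4aos, Serpina4-ps1, Dct, Clec2h, Sntg2, Rd3 and Lrit2 changed by -3.79, -3.70, -3.06, -2.96, -2.55, -1.58 and -1.35. The Slco1a1 probe lies on chromosome 6 from 141961072 to 141961131 and the Hsd3b5 probe on chromosome 3 from 98414360 to 98414419. The CFD diet arrays well above background numbered 2 for Slco1a1 (replicates 1 and 2) and Dct and 1 for Hnf4aos, Rd3 and Lrit2.

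**Figure D1:**
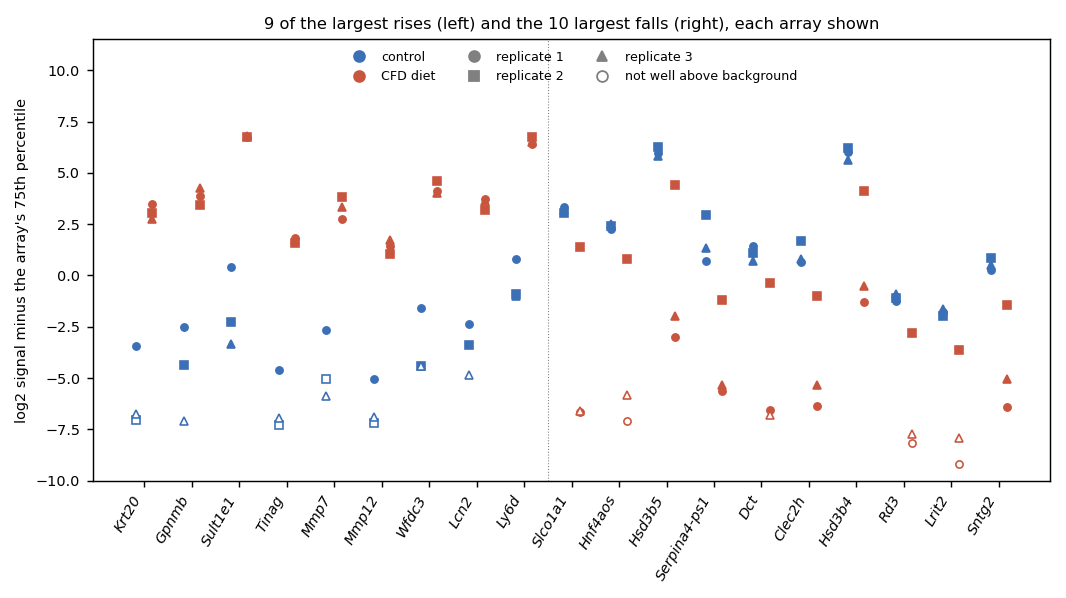
Each point is 1 array's log2 signal minus that array's 75th percentile, for 9 of the largest rises and the 10 largest falls. Blue points are control livers, red points CFD diet livers, shapes are replicates and open points are not well above background. CFD diet replicate 2 lies above the other CFD diet livers for Slco1a1, whose standard deviation in that group is 4.64.

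Genes of methionine and folate metabolism, which use the nutrients the diet lacks or limits, moved in both directions. Mat2a, the S-adenosylmethionine synthetase of non-hepatic and proliferating cells, rose by 2.18 ± 0.12 (adjusted p by limma = 9.63e-05). The mitochondrial folate enzymes Mthfd1l and Mthfd2 rose by 1.86 ± 0.18 and 2.37 ± 0.28, while the cytosolic Mthfd1 changed by -1.59 ± 0.21. Mthfd2 was well above background on 2 of the 3 control arrays. Of 37 tested genes, 8 rose and 19 fell, and adjusted over the list alone 9 rose and 21 fell. The list as a whole did not pass camera (adjusted p = 0.138), and it passed without CFD diet replicate 2 (adjusted p = 0.0383). Of 29 choline and phospholipid genes, 4 rose and 12 fell, or 4 and 14 adjusted over the list alone. Pctp, which transfers phosphatidylcholine, changed by -1.78 ± 0.15 and Aldh7a1, which oxidizes betaine aldehyde, by -2.23 ± 0.29. The lysophosphatidylcholine acyltransferase Lpcat2 rose by 1.34 ± 0.16. The choline transporter-like gene Slc44a4 was at least 4.34-fold higher, as it was not well above background in the controls. Another Slc44a4 probe, also not well above background in the controls, was at least 3.325-fold higher. Pemt, which methylates phosphatidylethanolamine to phosphatidylcholine and was picked out after its value was seen, did not pass the test (0.04 ± 0.15), but passed upward after quantile normalization, at 0.46 (adjusted p = 0.0170). This list did not pass camera either (adjusted p = 0.0989), and it passed without CFD diet replicate 2 (adjusted p = 0.0383). With normexp, both lists passed (adjusted p = 0.0438 and 0.0322), and Mthfd2 and Slc44a4 had log2 fold changes of 0.95 and 0.60.

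**Figure D2:**
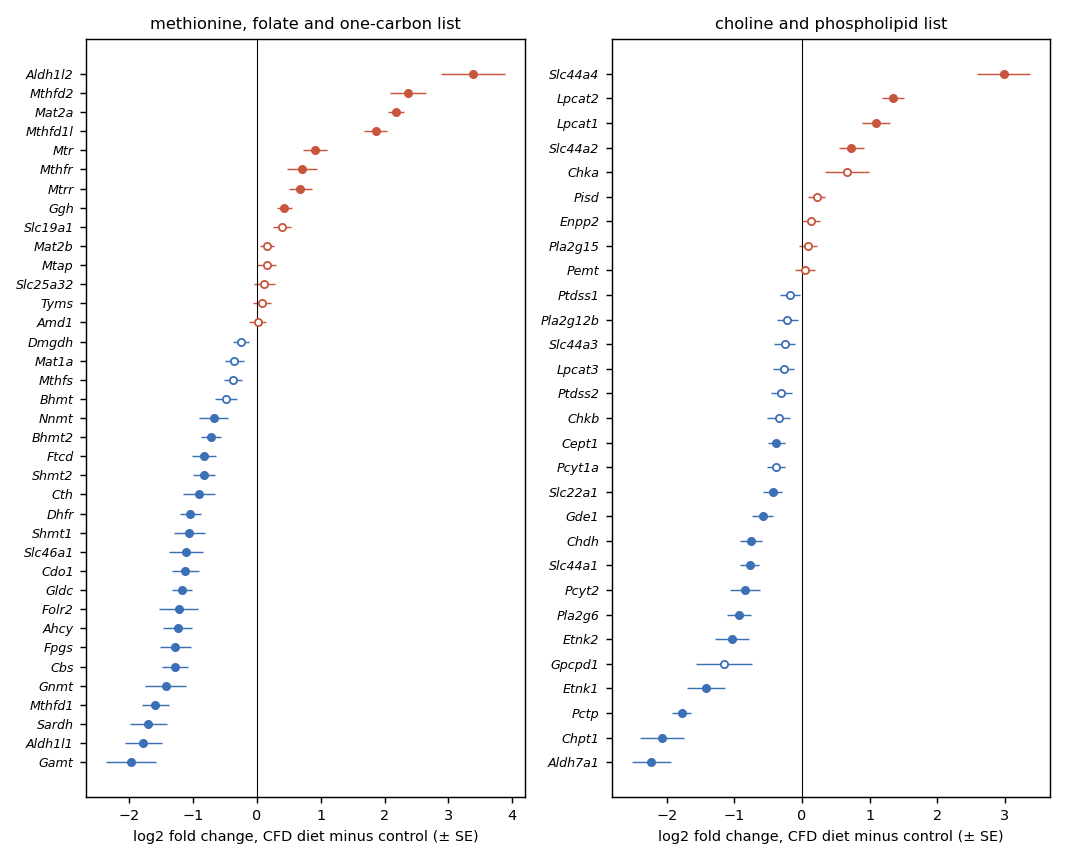
Log2 fold changes of CFD diet minus control for the members of the methionine and folate list and of the choline and phospholipid list, with standard errors from limma and 3 arrays per group. Red points are higher and blue points lower in the CFD diet livers, and filled points passed an adjusted p of 0.05. Mat2a (2.18) and Mthfd2 (2.37) are among the rises and Mthfd1 (-1.59) among the falls.

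Genes of cholesterol synthesis fell together, with 23 of 28 lower and 0 higher, also adjusted over the list alone. Cyp51 and Hmgcs1, enzymes of the sterol pathway, changed by -1.55 ± 0.17 and -1.11 ± 0.16 and the sterol carrier Stard4 by -2.07 ± 0.27. Camera gave the list an adjusted p of 2.42e-06, and adjusted p = 0.539 with an estimated correlation. Its mean differed by -1.36, -0.74 and -1.41 within the 3 slides. After quantile normalization Hmgcs1 changed by -0.66. Of 33 genes of fatty acid and triglyceride synthesis, 21 fell and 5 rose, or 23 and 5 adjusted over the list alone. The elongase Elovl6 changed by -1.70 ± 0.19, whereas the desaturase Scd2 rose by 2.07 ± 0.14, Lpin3 by 1.40 ± 0.14 and the acyltransferase Gpat3 by 2.30 ± 0.24. Fads2 and Elovl1, named after their values were seen, were the other 2 that rose. Camera gave this list an adjusted p of 0.00762, and adjusted p = 0.663 with an estimated correlation, and fry did not call it (adjusted p = 0.0939). The mean differed by -1.19, -0.26 and -1.49 within the slides.

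Of 47 genes of fatty acid oxidation and PPARA targets, 25 fell and 7 rose, or 26 and 8 adjusted over the list alone. The acyl-CoA thioesterase Acot2 rose by 2.83 ± 0.17, the hormone Fgf21 by 3.09 ± 0.35, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose as well (adjusted p by limma = 0.000337). The list fell by camera at an adjusted p of 0.0369, and adjusted p = 0.737 with an estimated correlation. Its mean was -0.26, 0.04 and -0.44 within the slides, and the call ended with the slide as a block (adjusted p = 0.0532), without control replicate 3 (adjusted p = 0.101) and without CFD diet replicate 3 (adjusted p = 0.0542). It ended too in 4 other settings, and quantile normalization turned the mean to 0.10 (adjusted p = 0.489). Of 31 genes of lipid droplets, uptake and export, 11 rose and 10 fell, also adjusted over the list alone. The lipoprotein Apoa4 rose by 5.23 ± 0.16, the fatty acid binding protein Fabp4 by 1.79 ± 0.14, the fatty acid translocase Cd36 by 1.75 ± 0.16 and the droplet coat protein Plin5 by 1.39 ± 0.13. This list did not pass camera (adjusted p = 0.496), with a median of -0.01 and a mean of 0.43 (0.22 to 0.70 over the settings).

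Of 34 bile acid genes, 23 fell and 4 rose, or 24 and 4 adjusted over the list alone. Abcb11, the canalicular bile salt export pump, changed by -1.41 ± 0.19. The 4 that rose were Slc51b, a subunit of the basolateral bile acid exporter, by 4.03 ± 0.19, the efflux transporter Abcc4 by 3.11 ± 0.32, the oxysterol hydroxylase Cyp39a1 by 1.38 ± 0.18 and Abcb1a, named after its value was seen and well above background on 1 control array, by 2.21 ± 0.39. The list had an adjusted p of 0.000870 by camera, and adjusted p = 0.578 with an estimated correlation. The mean differed by -1.36, -0.45 and -1.46 within the slides. With normexp, Slc51b rose by 2.61 and Abcb1a by 0.68, and after quantile normalization Abcb11 changed by -0.91.

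Hepatocyte genes fell in the CFD diet livers. Of 40 genes for secreted proteins, amino acid and urea cycle enzymes, 31 fell and 1 rose, or 34 and 1 adjusted over the list alone. Plg, which encodes plasminogen, changed by -1.48 ± 0.22, the glucose-6-phosphatase gene G6pc by -1.16 ± 0.18, the asialoglycoprotein receptor gene Asgr2 by -1.35 ± 0.22 and Fah, of tyrosine breakdown, by -1.37 ± 0.23. The gene that rose was Hpx, for hemopexin, by 0.49 ± 0.14. The list's adjusted p by camera was 2.16e-07, and adjusted p = 0.578 with an estimated correlation. The mean differed by -1.16, -0.57 and -1.36 within the slides. After quantile normalization the mean of the list was -0.57 and G6pc changed by -0.69. The call of Hpx ended with the slide as a block (adjusted p by limma = 0.0688) and in 7 other settings.

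Of 46 drug-metabolizing P450 and flavin monooxygenase genes, 34 fell and 7 rose, also adjusted over the list alone. Cyp4v3 changed by -1.61 ± 0.19. Cyp2b9, a female-biased P450, rose by 2.00 ± 0.15, and Cyp1b1, well above background on 1 control array, by 2.88 ± 0.27. In camera the list reached an adjusted p of 0.000212, and adjusted p = 0.628 with an estimated correlation. The mean differed by -1.14, -0.44 and -1.23 within the slides. Genes that are higher in male than in female mouse liver fell, 23 of 26 with 0 rising, or 25 adjusted over the list alone. Cyp4a12a changed by -1.18 ± 0.16, Ces2e by -1.12 ± 0.16, and the glucuronosyltransferases Ugt2b1 and Ugt2b38 by -1.98 ± 0.32 and -1.77 ± 0.31. Of 26 female-biased genes, 17 rose and 7 fell, or 18 and 7 adjusted over the list alone. Besides Cyp2b9, the sulfotransferase Sult2a2 rose by 6.82 ± 0.55, well above background on 1 control array, and Cd36 by 1.75 ± 0.16. The male-biased list had an adjusted p of 5.78e-06 by camera, and adjusted p = 0.578 with an estimated correlation. The female-biased list had 0.00189, and adjusted p = 0.357 with an estimated correlation. The male-biased mean differed by -3.46, -1.30 and -3.36 and the female-biased mean by 1.40, 1.89 and 1.48 within the slides. The female-biased mean was 0.79 where only probes well above background on all 6 arrays were kept, and with normexp Cyp1b1 rose by 0.93 and Sult2a2 by 3.44. A second bright probe for Cyp4a12a gave -4.52 ± 1.16, and after quantile normalization Cyp4a12a changed by -0.77.

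Of 49 NRF2 target, glutathione and conjugation genes, 15 rose and 25 fell, or 16 and 26 adjusted over the list alone. The plasma glutathione peroxidase Gpx3 rose by 3.57 ± 0.13, Mgst2 by 4.89 ± 0.26, Gpx2, well above background on 2 control arrays, by 2.53 ± 0.14 and Cbr3 by 2.39 ± 0.16. The list did not pass camera (adjusted p = 0.563), with a median of -0.47, a mean of 0.05 (-0.15 to 0.38 over the settings) and a direction that was down by camera and up by fry. Of 32 acute phase genes, 9 rose and 11 fell, or 10 and 11 adjusted over the list alone. Apcs, which encodes serum amyloid P, rose by 3.21 ± 0.15, the metallothioneins Mt2 and Mt1 by 4.98 ± 0.26 and 3.26 ± 0.19 and the endotoxin co-receptor Cd14 by 2.85 ± 0.15. That list did not pass camera (adjusted p = 0.769), with a median of -0.23 and a mean of 0.37 (0.16 to 0.67 over the settings). Of 26 iron genes, 5 rose and 6 fell, also adjusted over the list alone. Besides Lcn2, Id1 rose by 2.30 ± 0.29, and the iron regulatory genes Aco1 and Ireb2 changed by -1.10 ± 0.15 and -0.92 ± 0.13. The iron list did not pass camera (adjusted p = 0.979), with a median of -0.05, a mean of 0.30 (0.03 to 0.53 over the settings) and a direction that was up by camera and down by fry. Of 20 circadian genes, 11 fell and 1 rose, also adjusted over the list alone. The repressors Per3 and Cry2 changed by -1.81 ± 0.25 and -1.01 ± 0.17 and the clock output Usp2 by -2.25 ± 0.43, while the activator Arntl rose by 2.13 ± 0.38. Per3 was well above background on 1 CFD diet array. Camera gave the circadian list an adjusted p of 0.0130, and adjusted p = 0.369 with an estimated correlation, and its mean differed by -0.88, -0.48 and -0.84 within the slides. With normexp, Mgst2 rose by 3.18 and Gpx2 by 1.06, and Per3 lost its call at -0.31, while after quantile normalization Aco1 changed by -0.66. Other bright probes gave -0.29 ± 0.19 for Ireb2 and -0.33 ± 0.16 for Cry2 and did not pass.

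Genes of the extracellular matrix and fibrosis rose, 49 of 53, while Fn1, Col5a3 and Col18a1, named after their values were seen, fell. The counts were the same adjusted over the list alone. Spp1, which encodes osteopontin, rose by 3.99 ± 0.21 and Ltbp2 by 3.90 ± 0.25. Thbs1, for thrombospondin, was at least 5.53-fold and the collagenase gene Mmp13 at least 10-fold higher, as neither was well above background in the controls. Other Thbs1 probes gave 1.29 ± 0.47 and 0.85 ± 0.53 in a fit of all probes and did not pass. They were well above background on 2 and 1 CFD diet arrays and on 0 control arrays. Camera gave the matrix list an adjusted p of 2.41e-14, and adjusted p = 0.357 with an estimated correlation. The mean rise was 1.73, 1.86 and 2.41 within the slides. Of 21 stellate cell and myofibroblast markers, 16 rose, and Ecm1 and Tpm2, named after their values were seen, fell, also adjusted over the list alone. Vim, for vimentin, rose by 2.58 ± 0.17, the smooth muscle genes Tagln and Tpm1 by 2.39 ± 0.17 and 1.61 ± 0.13 and the growth factor receptor gene Pdgfra by 2.11 ± 0.22. The list had an adjusted p of 2.44e-05 by camera, and adjusted p = 0.207 with an estimated correlation, with slide means from 0.86 to 1.11. With normexp the mean of the matrix list was 1.32, and Thbs1, Mmp13 and Pdgfra had log2 fold changes of 0.88, 1.44 and 1.39. The calls of Fn1 and Ecm1 ended after quantile normalization (adjusted p by limma = 0.0582 and 0.785), where Col18a1 changed by -0.41, and those of Ecm1 and Tpm2 without the filter on dim probes and without control replicate 3 or CFD diet replicate 3. The call of Ecm1 also ended without control replicate 2 and that of Tpm2 without CFD diet replicate 1.

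Markers of recruited macrophages and monocytes rose, 32 of 36 with 0 falling, also adjusted over the list alone. The tetraspanin Cd63 rose by 4.46 ± 0.14, galectin 3 (Lgals3) by 4.55 ± 0.20, the lipid receptor Trem2 by 6.02 ± 0.27 and the fungal glucan receptor Clec7a by 4.13 ± 0.22. The list's adjusted p by camera was 2.67e-13, and adjusted p = 0.369 with an estimated correlation, with slide means of 2.14, 2.01 and 3.04. Of 15 markers of resident Kupffer cells, 7 rose and 4 fell, or 7 and 6 adjusted over the list alone. Spic, a transcription factor of iron-recycling macrophages, rose by 1.38 ± 0.17, the complement genes C1qb and C1qc by 1.25 ± 0.18 and 0.99 ± 0.15 and Id3 by 0.83 ± 0.14. The Kupffer list did not pass camera (adjusted p = 0.346), with a median of 0.26 and a mean of -0.09 (-0.29 to 0.13 over the settings). Of 11 neutrophil markers, 10 rose and 0 fell, also adjusted over the list alone. S100a8 and S100a9 rose by 3.85 ± 0.21 and 3.72 ± 0.23, Retnlg, well above background on 1 control array, by 2.97 ± 0.14 and Clec4d, on 2 control arrays, by 6.03 ± 0.37. In camera the list reached an adjusted p of 3.92e-06, and adjusted p = 0.357 with an estimated correlation, with slide means of 3.42, 2.67 and 4.06. With normexp the neutrophil mean was 2.03 and Retnlg rose by 1.20, and the mean was 1.99 where only probes well above background on all 6 arrays were kept.

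Of 38 chemokine, cytokine and innate receptor genes, 26 rose and 7 fell, also adjusted over the list alone. The monocyte chemoattractant Ccl2 rose by 4.47 ± 0.30, Ccl3, well above background on 1 control array, by 5.20 ± 0.35, Ccl6 by 2.32 ± 0.15 and the interleukin 1 receptor antagonist Il1rn by 3.12 ± 0.19. Camera gave an adjusted p of 5.78e-06, and adjusted p = 0.404 with an estimated correlation, with slide means of 0.93, 1.21 and 1.64. Of 32 interferon-stimulated genes, 8 rose and 5 fell, also adjusted over the list alone. Oasl1, Oas1a and Usp18 rose by 1.63 ± 0.25, 0.83 ± 0.18 and 1.02 ± 0.24 and B2m changed by -0.70 ± 0.15. Another bright probe for B2m gave 0.20 ± 0.22, and B2m lost its call after quantile normalization (adjusted p by limma = 0.0943), as did Usp18 without the filter on dim probes (adjusted p = 0.0514). The interferon list did not pass camera (adjusted p = 0.712), and its mean was -0.45, 0.00 and 0.86 within the slides. Of 25 lymphocyte markers, 2 rose and 4 fell, or 2 and 3 adjusted over the list alone. The natural killer receptor Klrd1 rose by 2.08 ± 0.31 and perforin (Prf1), well above background on 2 control arrays, by 1.38 ± 0.27. The T cell kinase Zap70 changed by -1.62 ± 0.34. The lymphocyte list did not pass camera (adjusted p = 0.352), with slide means of -0.67, -0.28 and 0.15. With normexp, Ccl3 rose by 2.15 and Klrd1 by 1.26, and Prf1 lost its call at 0.44.

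Endothelial markers moved the other way from those of macrophages, with 12 of 25 lower and 3 higher, also adjusted over the list alone. Kdr, a receptor of vascular endothelial growth factor, changed by -1.14 ± 0.13 and the sinusoidal nuclease gene Dnase1l3 by -1.48 ± 0.19. Lyve1, a sinusoidal and lymphatic hyaluronan receptor, rose by 1.74 ± 0.18 and Cd34, a marker of capillary endothelium, by 2.54 ± 0.27, and Plvap, named after its value was seen, rose as well. Camera gave the list an adjusted p of 0.0206 downward, and adjusted p = 0.369 with an estimated correlation, with slide means of -0.35, -0.18 and -0.29. The call ended where only probes well above background on all 6 arrays were kept (adjusted p = 0.0541). Of 7 erythrocyte markers, 4 fell and 0 rose, also adjusted over the list alone. Car1 changed by -2.17 ± 0.37, Slc4a1 by -1.27 ± 0.23, Alas2 by -1.61 ± 0.30 and Klf1 by -1.89 ± 0.39. The list had an adjusted p of 0.0206 by camera, and adjusted p = 0.578 with an estimated correlation, with slide means of -1.39, -0.88 and -1.42. Of 7 pancreas and adipose markers, 4 fell and 1 rose, also adjusted over the list alone. Cela1 rose by 2.34 ± 0.16, and Cela2a, Car3 and Amy2 changed by -2.15 ± 0.30, -2.88 ± 0.69 and -1.16 ± 0.29. Cela2a was well above background on 1 CFD diet array, and Cfd, named after its value was seen, was the other that fell. The list did not pass camera (adjusted p = 0.365), with slide means of -2.21, -0.14 and -2.17. With normexp, Klf1 changed by -1.04 and Cela1 by 1.45, and Slc4a1 and Cela2a lost their calls at -0.50 and -0.30. The calls of Plvap and Cfd ended with the slide as a block (adjusted p by limma = 0.0632 and 0.0750) and without any array other than CFD diet replicate 2, except that of Plvap without control replicate 2, and that of Amy2 ended without the filter on dim probes.

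**Figure D3:**
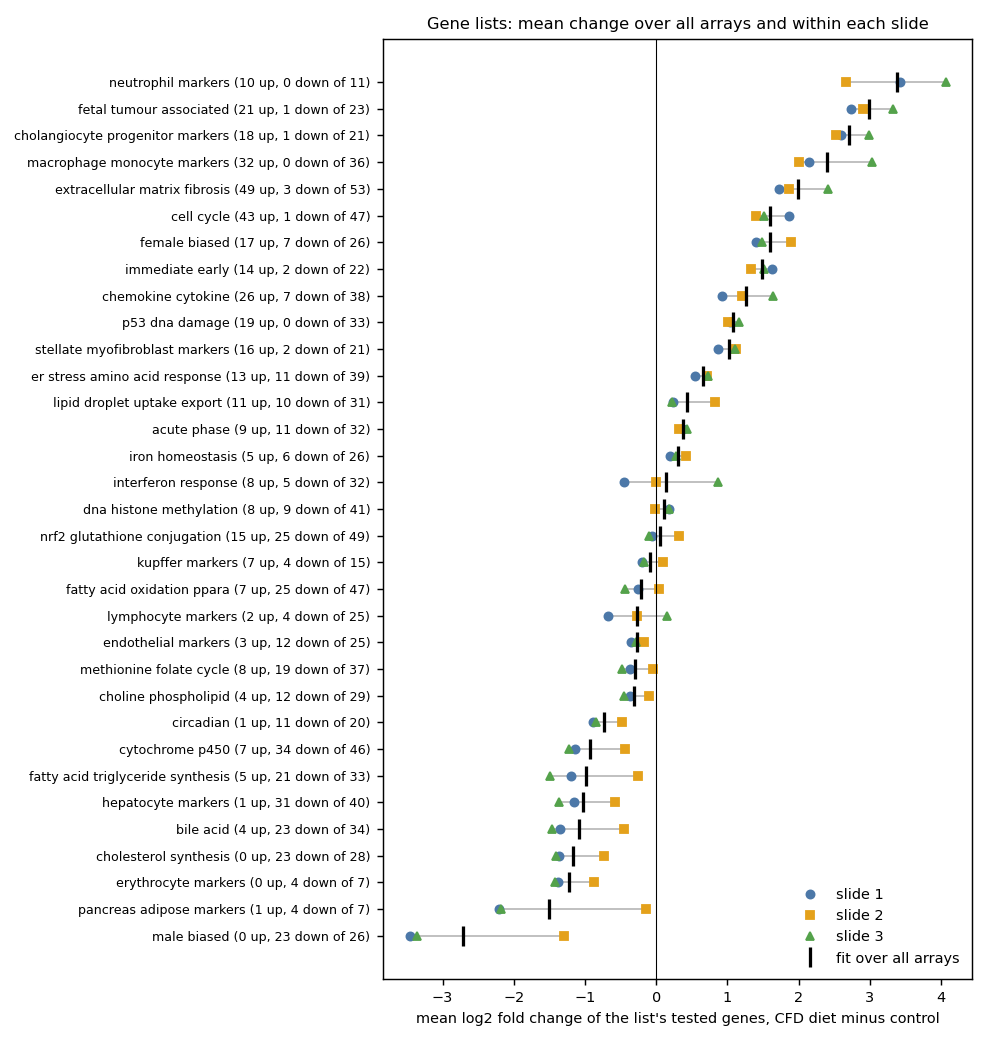
Mean log2 fold change of CFD diet minus control over the tested genes of each of the 33 lists, within each slide (coloured points, 1 control and 1 CFD diet array each) and over all arrays (black ticks). Row names give the genes called higher and lower by limma. Macrophage markers rose within every slide (2.14, 2.01 and 3.04) and male-biased genes lay lowest (-3.46, -1.30 and -3.36).

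Cell cycle genes rose, 43 of 47, and Tk1, named after its value was seen, fell. Adjusted over the list alone, 44 rose and 1 fell. The proliferation marker Mki67 rose by 2.46 ± 0.23, the spindle genes Nusap1 and Kif22 by 2.71 ± 0.25 and 1.87 ± 0.15 and the checkpoint kinase gene Bub1b by 1.77 ± 0.16. The list's adjusted p by camera was 3.32e-13, and adjusted p = 0.357 with an estimated correlation, with slide means of 1.86, 1.40 and 1.52. Of 33 p53 target and DNA damage genes, 19 rose and 0 fell, or 20 and 0 adjusted over the list alone. The cyclin-dependent kinase inhibitor Cdkn1a rose by 3.82 ± 0.30, Phlda3 by 3.35 ± 0.15 and the death receptor gene Tnfrsf10b, well above background on 1 control array, by 3.00 ± 0.25. In camera the list reached an adjusted p of 1.88e-05, and adjusted p = 0.369 with an estimated correlation, with slide means of 1.04, 1.00 and 1.17. With normexp the cell cycle mean was 1.05, and Nusap1, Bub1b and Tnfrsf10b rose by 1.53, 0.83 and 0.90.

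Genes associated with fetal liver and liver tumours rose, 21 of 23, and Tff3, named after its value was seen, fell. Afp, which encodes alpha-fetoprotein, rose by 5.75 ± 0.26, annexin 2 (Anxa2) by 4.13 ± 0.19 and the surface glycoprotein Cd24a by 3.79 ± 0.22. Bex1 was at least 15.6-fold higher, as it was not well above background in the controls. Camera gave an adjusted p of 6.79e-11, and adjusted p = 0.334 with an estimated correlation, with slide means of 2.74, 2.91 and 3.33. Of 21 cholangiocyte and ductular markers, which share 5 genes with that list, 18 rose, and Onecut1, named after its value was seen, fell. The tight junction gene Cldn7 rose by 3.98 ± 0.19 and the tetraspanin Tspan8 by 5.32 ± 0.32. The epithelial transcription factor gene Ehf was at least 5.65-fold higher, with no control array well above background. Other Ehf probes, with no control array well above background either, were at least 2.37-fold and 6.38-fold higher. The list had an adjusted p of 3.86e-09 by camera, and adjusted p = 0.207 with an estimated correlation, with slide means of 2.60, 2.52 and 2.98. For both lists the counts adjusted over the list alone were the same. With normexp the mean of the cholangiocyte list was 1.43, and Bex1, Ehf and Tff3 had log2 fold changes of 1.8, 0.95 and -1.21. The call of Onecut1 ended with trend and robust settings, without the filter on dim probes and without any of the 3 CFD diet arrays.

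Of 39 genes of the unfolded protein and amino acid responses, 13 rose and 11 fell, or 13 and 12 adjusted over the list alone. The serine synthesis enzymes Psat1 and Phgdh rose by 5.43 ± 0.26 and 3.69 ± 0.21, the stress protein Nupr1 by 5.85 ± 0.30 and the transcription factor Atf3 by 4.54 ± 0.25. The list did not pass camera (adjusted p = 0.348), with a median of 0.00 and a mean of 0.66. Of 22 immediate early genes, a list that responds to tissue handling, 14 rose, and Nr4a2 and Zfp36, named after their values were seen, fell, also adjusted over the list alone. Besides Atf3, Ier3 rose by 3.60 ± 0.22, Fos, well above background on 1 control array, by 3.20 ± 0.20 and Egr2, on 2 control arrays, by 5.14 ± 0.34. The list's adjusted p by camera was 0.000202, and adjusted p = 0.357 with an estimated correlation, with slide means of 1.63, 1.33 and 1.52. Of 41 genes of DNA and histone methylation, 8 rose and 9 fell, or 7 and 9 adjusted over the list alone. The tRNA methyltransferase Trdmt1 rose by 1.94 ± 0.12, Uhrf1, which recruits the maintenance DNA methyltransferase, by 2.50 ± 0.17 and the histone methyltransferase Suv39h2, well above background on 1 control array, by 1.22 ± 0.18. Tet1, which oxidizes methylcytosine, changed by -2.09 ± 0.31. This list did not pass camera (adjusted p = 0.543). With normexp, Ier3, Fos, Egr2 and Uhrf1 rose by 1.85, 0.93, 3.36 and 1.39, Nr4a2 changed by -0.76 and Suv39h2 lost its call at 0.24. The call of Zfp36 ended in 6 settings, among them the mean of a gene's probes (adjusted p by limma = 0.0523).

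Across the 33 lists, camera with the preset correlation called 21, with 11 higher and 10 lower, and fry called 23. With an estimated correlation camera called 0, and 4 lists had an unadjusted p under 0.05. Each of the other groupings of the 6 arrays into 3 and 3 sets 2 arrays of a diet and 1 of the other against the reverse. Such a grouping keeps part of the diet difference and also puts it into the spread within groups. Among these groupings, camera with the preset correlation called between 7 and 22 lists while limma called 0 genes.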

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

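Centring on the median of tested genes was the 1 setting added after seeing the data. Over the settings that fit 1 probe or 1 mean per gene, limma called between 5499 genes (no filter on dim probes) and 10197 genes (array weights), and between 5858 and 9034 with an array left out. Counting every probe, it called 11669 of 23482. With normexp on mean and local background signals, 2189 genes changed at least 2-fold. Without the filter on dim probes, 27670 genes were tested and 2459 were lower in the CFD diet livers. With an array left out, the genes lower in the CFD diet livers ranged from 2746 without control replicate 3 to 4847 without CFD diet replicate 2, and were 2844 without CFD diet replicate 3. Camera called between 19 and 23 lists over the settings and 0 with an estimated correlation (4 at an unadjusted p under 0.05, and 23 by fry). With the replicate block, 7319 genes were called, 7046 of them among the 8129, and the fatty acid oxidation list was the 1 list call lost. Replicates with the same number correlated at 0.174, -0.07 and -0.01 across the deviations from the group means, and only number 1 had its own partner as the closest, so the numbers are no evidence of pairs.

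List means changed sign as follows, and the cause was not tested. The mean of the NRF2 and glutathione list was -0.11 with normexp, -0.15 with median scaling, -0.0937 with probes well above background on all 6 arrays and -0.0373 with array weights, and ranged from -0.15 to 0.13 with an array left out. Quantile normalization gave 0.10 for fatty acid oxidation and 0.13 for Kupffer markers. Median scaling gave -0.0892 for DNA and histone methylation and -0.0671 for the interferon list. With an array left out, the interferon list ranged from -0.19 to 0.35 and the Kupffer list from -0.29 to 0.0311. Of these lists, only fatty acid oxidation had passed camera. It also lost its call with median scaling, without the filter on dim probes, with probes well above background on all 6 arrays and with the mean of a gene's probes. Over the settings, means that kept their sign ranged, for example, from -0.52 to -0.17 for choline, -0.50 to -0.05 for methionine, -0.47 to -0.10 for lymphocytes, -2.04 to -0.51 for pancreas and adipose and -0.48 to -0.22 for endothelial markers. They ranged from -1.27 to -0.57 for hepatocyte, 1.43 to 2.82 for cholangiocyte, 0.79 to 1.94 for female-biased and 1.99 to 3.70 for neutrophil genes. The choline and methionine lists passed with normexp (adjusted p = 0.0322 and 0.0438).

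None of the 145 genes named by the rule changed direction under the settings that tested it. Of 37 genes named after their values were seen, Pemt, which did not pass, was -0.16 with median scaling and ranged from -0.053 to 0.14 with an array left out, and the cause was not tested. The offset of normexp brings dim values closer together by its construction. Per3, Suv39h2, Slc4a1, Prf1 and Cela2a lost their calls with normexp, B2m with quantile normalization, and Slco1a1, Hnf4aos, Hsd3b5 and Dct with trend and robust settings. Without the filter on dim probes, these 4 genes, Clec2h, Hsd3b4, Rd3, Lrit2, Usp18 and Amy2 lost theirs. Signal over background limits the dim genes, since 274 called genes were not well above background on any control array and 10 on any CFD diet array.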

Other observations

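Gene families were formed by symbol stem after the data had been seen, and camera with the preset correlation shifted 15 of 157, with an adjusted p of 0.963 for each with an estimated correlation. Of 16 tested hydroxysteroid dehydrogenase genes (Hsd), 14 fell and 0 rose, with a median of -1.48. Hsd3b6 changed by -1.99 ± 0.26, Hsd3b3 by -1.88 ± 0.27 and Hsd17b2 by -1.57 ± 0.27. Of 14 genes with the stem Ugt, mostly glucuronosyltransferases, 13 fell, with a median of -1.72. Ugt1a1 changed by -1.34 ± 0.15 and Ugt1a9 by -2.69 ± 0.41. Ugt8a, which encodes a galactosyltransferase and not a glucuronosyltransferase, was at least 2.40-fold higher. It had no control array well above background and lost its call with normexp. Of 13 carboxylesterase genes (Ces), 11 fell, and Ces4a rose by 2.41 ± 0.23. Of 16 peroxin genes (Pex), 10 fell, such as Pex6 by -1.47 ± 0.22, and of 16 autophagy genes (Atg), 9 fell, such as Atg2a by -1.21 ± 0.18, with 0 rising in either family. The family medians kept their sign under all 4 scalings, with that of the peroxins moving from -0.61 to -0.39 after quantile normalization.

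Annexins, keratins, genes with the stem Itgb and tumour necrosis factor receptors rose. Of 11 annexin genes, 7 rose and 2 fell, with Anxa1 up by 3.28 ± 0.19, Anxa13 by 3.23 ± 0.24 and Anxa3 by 2.55 ± 0.20. Of 15 keratin genes, 10 rose and 1 fell, with the ductular Krt19 up by 3.65 ± 0.35, Krt7 by 3.25 ± 0.47, Krt23 by 2.91 ± 0.21 and Krt8 by 1.09 ± 0.13. Of 10 genes with the stem Itgb, 7 rose and 0 fell. The stem holds beta integrins and also Itgb3bp, which is not an integrin. The leukocyte integrin Itgb2 rose by 2.35 ± 0.26 and the epithelial Itgb4 by 1.81 ± 0.22. Of 16 receptor genes of the tumour necrosis factor family (Tnfrsf), 10 rose and 1 fell, with Tnfrsf12a up by 2.14 ± 0.16. Of 28 kinesin genes, 18 rose and 2 fell, with Kif20a up by 1.93 ± 0.23. The medians of these families kept their sign under all 4 scalings too. With normexp those of the kinesins and Tnfrsf shrank from 1.07 to 0.34 and 1.05 to 0.54. Those of the Itgb genes and keratins shrank with normexp from 1.17 to 0.62 and 1.42 to 0.84. Itgb4 rose by 1.15 with normexp and Krt8 by 1.65 after quantile normalization.

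Of the tests that follow, the slope for control replicate 1, its test on bright probes, the linear and log2 shares of CFD diet replicate 2 and both tests of cell types were chosen only after the result was seen. Control replicate 1 lay above controls 2 and 3 for genes that are high in the CFD diet livers, such as Krt20 and Mmp7. A set of 330 probes was well above background on all CFD diet arrays and on neither of the other controls. Their CFD diet mean was also higher than that of controls 2 and 3 by at least 3 on the log2 scale. Of these probes, 49.1% were well above background on control 1. The log2 signal of control 1 rose with that of CFD diet replicate 1 with a slope of 0.574 ± 0.045. Sets of probes chosen in the same way gave slopes of 0.162 for control 2 (194 probes) and 0.0333 for control 3 (214 probes). Each was fitted with the CFD diet liver of its own slide. A trace of CFD diet RNA stays open, since the slope of control 1 lies under the 0.7 set for a trace but above the bound set against it. The slopes of the other controls cannot decide this, as their sets leave out probes well above background on control 1. On control 1, 16 bright probes held a median of 2.19% of the CFD diet 1 signal (quartiles 1.16% and 2.55%). The slopes of control 1 on CFD diet 2 and 3 were as large (0.570 and 0.597), so no source liver stands out. A brighter array could account for the dim probes. Genes not raised by the diet lay 0.35 above the other controls and raised genes 0.46 (difference 0.113). These probes were chosen as not well above background on controls 2 and 3, which alone can place control 1 higher. The excesses therefore do not show a brighter array. Such an array could not account for the bright probes, whose excess was larger by 1.23 (bootstrap interval 0.76 to 2.34, 18 probes). A mild form of the same liver change in that mouse also stays open, as genes lowered at least 4-fold lay at a median of -0.0757 against the other controls, with an interval from -0.10 to -0.04 around the bound of -0.1.

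CFD diet replicate 2 kept more of the control level than the other CFD diet livers, for example for Slco1a1, Hnf4aos and Hsd3b5. On the log2 scale it lay 0.564 of the way back for 320 lowered genes and 0.0887 for 683 raised genes. This difference of 0.475 is over the 0.1 set for a compressed signal range on its array. It cannot decide the question, as such a range moves a gene by its signal level, which was not matched between raised and lowered genes. Scaling is argued against, as the share for lowered genes was 0.567 after quantile normalization. On the linear scale the shares were 0.301 for lowered genes (bootstrap interval 0.294 to 0.309) and 0.226 for raised genes (0.208 to 0.242). Their difference of 0.0752 is within the 0.1 set for control RNA mixed into this sample, but the intervals do not overlap. The quartiles of the raised genes were 0.05 and 0.38, and with normexp the shares were 0.312 and 0.154. Mixed-in control RNA therefore stays open and is not shown by these values. A liver in which part of the hepatocytes was spared was not tested and stays open.

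Markers of macrophages, cholangiocytes and stellate cells rose while hepatocyte genes fell. A lower share of hepatocyte RNA alone would raise every other cell type alike. The tables argue against it as the only cause, since macrophage markers exceeded endothelial markers by a mean of 2.67 on the log2 scale. That difference was 2.49, 2.19 and 3.32 within the slides (SD 0.588). It does not exclude a lower hepatocyte share as a contributor. For the rise of macrophage markers, scaling is argued against as well, since their lowest mean over the scalings was 1.99, with normexp. The hepatocyte fall was not tested in this way. Its mean was -1.24 with median scaling and -0.57 after quantile normalization, so its size depended on the scaling. A candidate explanation is a rise in macrophages and ductular cells themselves or in their expression, which whole liver RNA on these arrays cannot separate.

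Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed genes as the real one, which is the real split itself, with 8129 against a highest other count of 0. The same held for genes higher (3776 against 0), genes lower (4353 against 0) and genes changed at least 2-fold (3910 against 0), each with 1 of 10 splits. For gene lists called by camera, 2 of 10 splits reached the real count of 21, the other being control 1 with CFD diet 1 and 3, with 22. With 10 splits, the share cannot fall under 0.05, and each other split keeps part of the diet difference. Each also puts the diet difference into the spread within its groups, which lowers its count of genes, so the counts of 0 say little.

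The median log2 fold change went from 0.51 in the dimmest decile of the tested genes to -0.38 in the brightest. Of the called genes, 75.7% were higher in the CFD diet livers in the dimmest decile and 15.2% in the brightest. Camera did not match genes by signal level, so whether list directions follow this trend was not tested. After quantile normalization the medians went from 0.27 to 0.04, and camera called 20 lists. Of 92 tested olfactory receptor genes (Olfr), 29 fell and 4 rose. Among sex-linked genes looked at after the data had been seen, the brightest probes for Ddx3y and Eif2s3y were well above background on all 6 arrays and 3 of 4 Xist probes on 0 arrays.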
